A study of Mus musculus with 6 samples.

How the data were processed

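Total RNA from E14Tg2a mouse embryonic stem cells was measured at 96 h on Affymetrix arrays, per the labels after RNeasy (Qiagen) extraction and biotin labelling with an Affymetrix IVT kit. The cells had received a control siRNA against firefly luciferase, Ncl siRNA #1 or Ncl siRNA #2, and each group held 2 arrays. The deposited values are on a log2 scale and were already normalized between arrays by the authors, by a method that is not stated. Their range, 2.47 to 15.34 with array medians from 5.73 to 5.79, fits log2 probe set values, and no scaling was added for the main results. Background correction, summarisation and detection calls are not given in the sources used here, and nothing says whether replicates were separate cultures.

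Of 45101 probe sets, 34958 carried 1 gene symbol, 932 several and 9211 none, and 64 were control probe sets. Probe sets with 1 symbol were reduced to the one with the highest mean over all 6 arrays for each gene, which left 18194 genes, of which 9012 had more than 1 probe set. No symbol was changed through the gene identifier, and for 204 probe sets the identifier was not in the reference table. Probe sets with several symbols or none were left out of the gene tests, since their signal cannot be given to 1 gene. Trp53, T and Zscan4c, which had been fixed as genes to report, had no probe set of their own under this rule and were not analysed here.

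A linear model with 1 mean per group was fitted to all 6 arrays in limma 3.58.1 under R 4.3.3, with empirical Bayes variances that follow mean expression (trend). The residual degrees of freedom were 3 and the prior degrees of freedom 17.5. The contrasts were each Ncl siRNA minus control, the mean of both minus control, and siRNA #2 minus siRNA #1. P-values were adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05. With 2 arrays per group the precision is limited, and standard errors come from the pooled spread. The procedure was tested on simulated data with 200 changed genes, where it found 48 of 68 genes moved by 0.5 on the log2 scale, 65 of 66 moved by 1 and 66 of 66 moved by 2, with 13 false calls among 18194 genes.

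The 24 gene lists were written from general knowledge before the data were examined and tested with limma's camera at its preset correlation of 0.01, with Benjamini-Hochberg over the lists. Each was also tested with an estimated correlation and with fry. With an estimated correlation camera uses the 3 residual degrees of freedom, with which few lists can pass. A call lost there does not by itself argue against a list. Another 17 lists of marker genes for lung, blood and other organs, and 5 further lists (YAP and TEAD targets, SRF and actin cytoskeleton, imprinted genes, lysosome, simple epithelial adhesion), were written after the data were seen, and camera p-values of these 5 were adjusted over the 5. The effect of independent noise in the shared control arrays on the overlap was measured in 50 simulations without any siRNA effect.

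The rule for named genes was fixed before the data were examined. It named a fixed set of genes, the 12 highest and 12 lowest mean changes among genes called in the same direction with each siRNA, the 6 largest differences in each direction between the siRNAs, and up to 4 members of each list. Genes with only Gm or Rik names were passed over, which left out 1 among the 12 highest and 0 among the 6 highest differences. Those passed over among the lowest were not counted. Genes of the marker lists and of the 5 further lists were named outside this rule.

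Alternatives tried, 1 at a time, were quantile normalization of the deposited values, centring of each array on its median, the mean of all probe sets of a gene, leaving out probe sets ending in _x_at or _s_at, leaving out genes below the median signal, variances without a trend or with robust estimation, only the arrays of the groups compared, the replicate number as a block, array weights, at least 2-fold change, an adjusted p under 0.01, all probe sets, and leaving out each array in turn. Leaving out lung and heart muscle marker genes, and giving each siRNA 1 of the control arrays in a model with 4 groups, were added after the data were seen.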

Results

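Transcript levels were measured with Affymetrix arrays in E14Tg2a cells, a mouse embryonic stem cell line, at 96 h. The cells had received 1 of 3 small interfering RNAs, namely a control duplex against firefly luciferase, Ncl siRNA #1 or Ncl siRNA #2. Each group held 2 arrays, and every array gave 45101 probe set values on a log2 scale between 2.47 and 15.34, with array medians from 5.73 to 5.79. The median absolute difference between the arrays of a group was 0.12 for the control siRNA, 0.16 for Ncl siRNA #1 and 0.09 for Ncl siRNA #2. The number of arrays limits the precision, and nothing in the sources says that the replicates were separate cultures, so the p-values measure only the spread between these arrays. Changes are log2 differences with their standard errors (SE) from limma, and adjusted p-values cover 18194 genes.

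Genes of lung cells and added control RNAs separated the control siRNA arrays from all 4 Ncl siRNA arrays. Scgb1a1, the secretory protein of airway club cells, read 12.96 in both control arrays and between 3.29 and 4.01 in the Ncl siRNA arrays. Sftpc, the surfactant protein of alveolar type 2 cells, had a mean of 10.75 in the control arrays against 4.92 with siRNA #1 and 5.06 with siRNA #2. The bacterial poly-A controls, which are added to RNA before labelling, averaged 7.66 in the control arrays (SD 0.12, n = 2), 8.71 with siRNA #1 (SD 0.20, n = 2) and 8.42 with siRNA #2 (SD 0.05, n = 2). Probe sets for 18S ribosomal RNA averaged 12.10, 13.08 and 13.11 in the same order, and the hybridisation controls 12.03, 11.23 and 11.16. The 3′ minus 5′ difference of Actb, a sign of RNA quality, had a mean of 0.48 in the control arrays and 0.25 in the Ncl siRNA arrays, and that of Gapdh -0.03 and 0.00.

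**Figure D1:**
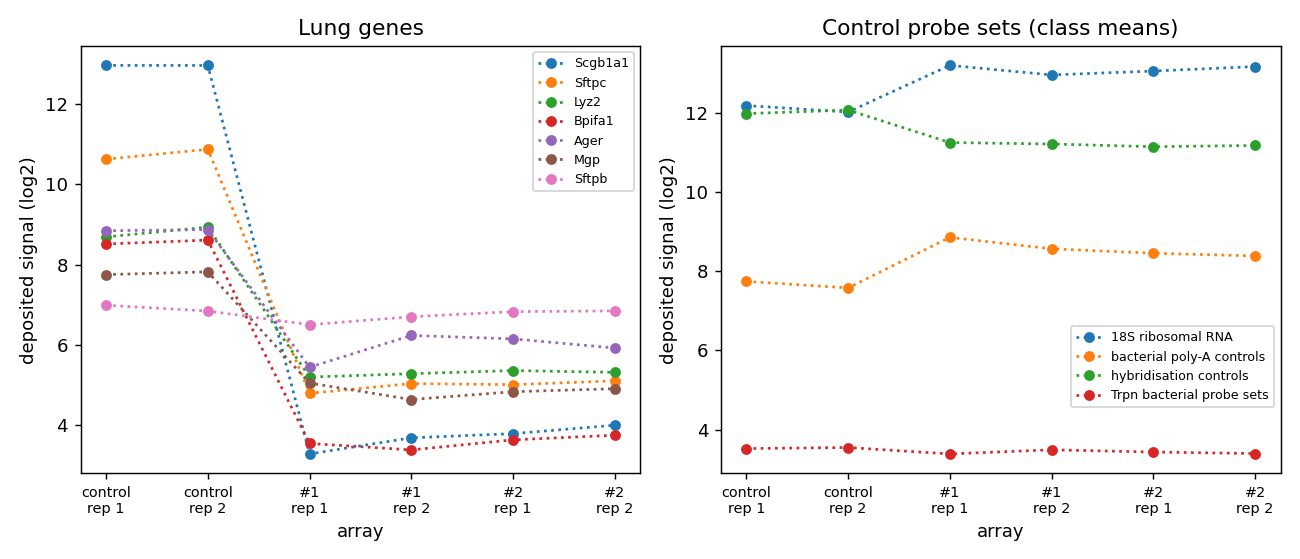
Deposited log2 signal (vertical axis) in each of the 6 arrays (horizontal axis) for 7 genes of lung cells on the left and the means of 4 classes of control probe sets on the right, with dotted lines that only join the points of 1 gene or class. Scgb1a1 read 12.96 in both control siRNA arrays and at most 4.01 in the Ncl siRNA arrays, while Sftpb, another surfactant gene read at a low level, stayed between 6.51 and 6.99 in all 6.

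Ncl, which encodes nucleolin, an abundant protein of the nucleolus needed for ribosome production, was measured first, to ask how far each siRNA lowered its target. The brightest of its 5 probe sets read 14.21 and 14.21 in the control arrays, 13.77 and 13.74 with siRNA #1 and 13.77 and 13.72 with siRNA #2. On this probe set Ncl fell by 0.46 with siRNA #1 (SE 0.04, n = 2 per group, limma adjusted p = 5.65e-09), to 72.9% of control. With siRNA #2 it fell by 0.46 as well (SE 0.04, n = 2 per group, limma adjusted p = 3.57e-09), to 72.5%. The other probe sets gave lower levels. In order of their mean signal in the control arrays, the probe set at 13.07 stood at 48.0% of control with siRNA #1 and 51.2% with siRNA #2, that at 11.57 at 37.2% and 33.6%, that at 10.95 at 62.9% and 69.0%, and that at 6.61 at 40.5% and 44.9%. Over the 5 probe sets the mean change was -0.98 with siRNA #1 and -0.94 with siRNA #2, and their difference was 0.04 (95% confidence interval -0.11 to 0.20 across probe sets). Probe sets of the same arrays are not replicates, so this interval measures only how far they disagree. Signals near the top of the measured range can compress differences, and nucleolin protein was not measured on these arrays.

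**Figure D2:**
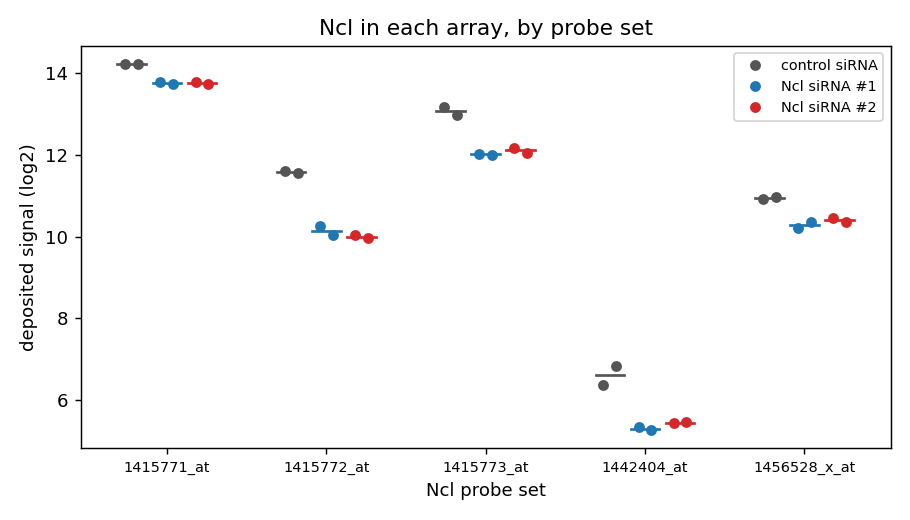
Deposited log2 signal (vertical axis) of the 5 Ncl probe sets (horizontal axis), with 1 point per array, colour for the siRNA and a bar at the mean of the 2 arrays of a group. Every Ncl siRNA array lay below both control arrays on all 5 probe sets, and on the brightest probe set Ncl fell by 0.46 with each siRNA.

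The mean of both Ncl siRNAs was then compared with the control siRNA (4 arrays against 2) to ask which transcripts changed when Ncl was targeted. Target genes of p53, genes of the trophectoderm, genes of the 2-cell-like state and germline genes rose, and genes of pluripotency, DNA replication and cholesterol synthesis fell. These group calls hold at camera's preset correlation, and all of them were lost with an estimated correlation. That test rests on 3 residual degrees of freedom. The germline list lost its call although its estimated correlation, -0.00929, lay below the preset 0.01, so a stronger correlation did not end that call. Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, rose 5.18-fold (log2 2.37, SE 0.06), and Mdm2, the ubiquitin ligase that acts on p53, rose 4.92-fold (log2 2.30, SE 0.04) on its brightest probe set, 2 of its 3 probe sets moving upwards. Pou5f1, the core pluripotency factor also called Oct4, fell by 0.46 (SE 0.04), and Nanog fell by 0.59 (SE 0.05). In all, 7647 of 18194 genes changed at an adjusted p under 0.05, of which 3702 rose and 3945 fell. Changes of at least 2-fold were met by 844 genes that rose and 292 that fell, and changes of at least 4-fold by 205 and 25. Of the 134 named genes that passed, 130 had all 4 Ncl siRNA arrays beyond both control arrays, the exceptions being Aspa, Otx2, Siglecf and Tdpoz1. Most named genes were chosen for the size of their change in these arrays, so this count does not describe other called genes.

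Among the genes that changed with each siRNA, the highest mean changes belonged to AF067061 (5.76, SE 0.07), Usp17la, a ubiquitin-specific protease gene of a repeated family (4.70, SE 0.09), and BC080696 (4.65, SE 0.12). AF067061 and BC080696 are known here only by sequence-record names. Pramel18, of the Prame-like family, followed with 4.41 (SE 0.11). Thbs1, the matrix protein thrombospondin, rose by 4.31 (SE 0.09) and Ccn1, a secreted matrix protein also called Cyr61, by 4.20 (SE 0.06). Plin2, a coat protein of lipid droplets, rose by 4.17 (SE 0.05), and Tmcc3 by 4.12 (SE 0.08). Nipal4 rose by 4.08 (SE 0.15), a call lost when probe sets ending in _x_at or _s_at were left out. Slc5a5, the sodium iodide symporter, rose by 3.98 (SE 0.10), Htra1, a secreted serine protease, by 3.93 (SE 0.07), and Arg2, the mitochondrial arginase, by 3.90 (SE 0.14). Both control readings of BC080696 and Nipal4 lay below the lower quartile of their arrays (4.32 and 4.31), so these rises are best read as lower bounds.

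The lowest mean changes belonged almost all to genes of lung cells. Scgb1a1 fell by 9.27 (SE 0.14), Sftpc fell by 5.76 (SE 0.13), Bpifa1, an airway secretory protein, fell by 4.98 (SE 0.15), and Scgb3a2, another airway secretoglobin, fell by 3.96 (SE 0.21). Lyz1 and Lyz2, lysozyme genes whose probe sets may read each other, fell by 5.88 (SE 0.17) and fell by 3.52 (SE 0.13), and the Lyz1 call was lost when probe sets ending in _x_at or _s_at were left out. Cbr2, Cyp2f2 and Ager, which mark lung epithelium, fell by 3.14 (SE 0.15), fell by 3.01 (SE 0.14) and fell by 2.92 (SE 0.16). Mgp, a matrix protein, fell by 2.93 (SE 0.15) and Inmt, a methyltransferase abundant in lung, fell by 2.73 (SE 0.19). Pdcl2, a phosducin-like gene, fell by 2.94 (SE 0.16). All Ncl siRNA readings of Scgb1a1, Bpifa1, Lyz1 and Cyp2f2 lay below the lower quartile of their arrays (4.17 to 4.31), so these falls are best read as lower bounds in each comparison against control. In lists of marker genes drawn up after these values were seen, 7 of 8 airway secretory genes were lower, with a list median of -3.08, and the list medians were -0.95 for alveolar type 2 cells, -0.98 for alveolar type 1 cells, -1.35 for lung mesenchyme, -0.87 for endothelium and -0.36 for macrophages and leukocytes. The median for ciliated cells was -0.02, with 2 of 6 genes lower and 2 higher, and for the 3 measured genes of red blood cells it was -0.09. Probe sets shared by several adult haemoglobin genes read -5.27, -4.77, -3.14 and -2.42. For heart muscle the median was -1.05, with 8 of 8 genes lower, and for the other organs it was -0.06 for liver, -0.02 for kidney, -0.02 for skeletal muscle, 0.03 for brain, -0.24 for pancreas, -0.11 for intestine, -0.13 for skin and -0.17 for testis. Of the 54 measured genes in the lung lists 27 read above 5.76, the mean of the array medians, in the Ncl siRNA arrays, among them Etv5, with a mean of 12.55 with siRNA #1, and Laptm5, with 11.02, and 4 also stand in lists fixed before (Etv5, Col3a1, Col1a2 and Dcn).

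Of 31 measured p53 target genes, 26 rose, 3 fell and 2 did not pass, and the counts were the same when adjusted over the list alone. The list rose as a group with a median of 0.89 (camera adjusted p = 8.17e-17, and adjusted p = 0.0819 with an estimated correlation). Cd80, a ligand of T cell co-stimulation, rose by 2.75 (SE 0.12), Pmaip1, the pro-apoptotic protein Noxa, by 2.62 (SE 0.06), Perp, a membrane protein of desmosomes, by 2.45 (SE 0.05) and Ccng1, cyclin G1, by 0.84 (SE 0.04). Among 22 apoptosis regulators 5 rose, 6 fell and 11 did not pass, also when adjusted over the list alone, and the list did not pass as a group (median 0.05, camera adjusted p = 0.557, and adjusted p = 0.606 with an estimated correlation). Its members Bik and Bcl2l11, both pro-apoptotic, rose by 0.95 (SE 0.13) and 0.82 (SE 0.06), and Bcl2l1, which opposes apoptosis, rose by 1.00 (SE 0.06), with 3 of its 4 probe sets moving upwards. Bmf, another pro-apoptotic gene, fell by 1.40 (SE 0.15) on the probe set used, but read 0.01 when probe sets ending in _x_at or _s_at were left out. The poly-A controls differed by 0.90 between the Ncl siRNA and control arrays, the same arrays in which these genes moved.

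All 12 measured genes of the 2-cell-like state, out of 24 in the list, rose, also when adjusted over the list alone (median 1.90, camera adjusted p = 5.19e-10). The adjusted p was 0.0819 with an estimated correlation. The list holds genes active in 2-cell embryos and in rare stem cells that resemble them, such as Tcstv3, which rose by 3.67 (SE 0.14) from control readings below the lower quartile of those arrays, and Zfp352, which rose by 3.04 (SE 0.11). Several belong to repeated families whose probe sets may read more than 1 gene. The control arrays that read them low were those with the lung transcripts and with 18S signals lower by 0.99. A probe set annotated to 6 symbols, among them members of the 2-cell-like list, read 6.61 and 6.75 in the control arrays and rose by 5.29 (SE 0.07) with siRNA #1 and by 6.50 (SE 0.07) with siRNA #2.

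Trophectoderm, the outer layer of the blastocyst, was represented by 20 measured genes, of which 16 rose, none fell and 4 did not pass, with the same counts when adjusted over the list alone. As a group they rose (median 1.21, camera adjusted p = 5.25e-11, and adjusted p = 0.0819 with an estimated correlation). Krt19, Krt18 and Krt8, keratins of simple epithelia, rose by 3.83 (SE 0.09), 3.71 (SE 0.06) and 3.53 (SE 0.05). The transcription factors Gata3, Eomes and Cdx2 rose by 2.90 (SE 0.17), 2.09 (SE 0.09) and 1.80 (SE 0.13). Germline genes rose as a group too (median 0.79, camera adjusted p = 6.21e-06, and adjusted p = 0.0819 with an estimated correlation), with 13 of 19 that rose, 1 that fell and 5 that did not pass, also when adjusted over the list alone. Taf7l, a testis form of a TFIID subunit, rose by 2.60 (SE 0.12), Slc25a31, a testis ADP/ATP carrier, by 2.46 (SE 0.14), Dazl, an RNA-binding protein of germ cells, by 1.66 (SE 0.12) and Mael, a factor in piRNA silencing, by 1.65 (SE 0.09). Against the same control arrays, airway secretory markers had a median of -3.08 and the poly-A controls a difference of 0.90.

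Of 28 genes in the list of pluripotency factors and markers, 16 fell, 7 rose and 5 did not pass, also when adjusted over the list alone, and the list fell as a group (median -0.25, camera adjusted p = 7.55e-04). That call was lost with an estimated correlation (adjusted p = 0.423 with an estimated correlation). Tcl1, a co-activator of Akt, fell by 2.06 (SE 0.08), and the transcription factors Prdm14, Tfcp2l1 and Nr5a2 fell by 1.37 (SE 0.10), fell by 1.33 (SE 0.07) and fell by 1.32 (SE 0.07). Klf4 fell by 0.61 (SE 0.05), Zfp42, also called Rex1, fell by 0.55 (SE 0.04), and Esrrb fell by 0.84 (SE 0.06) with 2 of its 3 probe sets moving downwards. Sox2 (-0.09, SE 0.05, adjusted p = 0.125) and Tbx3 (-0.07, SE 0.07, adjusted p = 0.490) did not pass. Sox2 did pass with each array centred on its median, and without replicate 2 of siRNA #1 or replicate 1 of siRNA #2. The control arrays of this comparison also held the lung transcripts, with Scgb1a1 at -9.27.

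Genes of the post-implantation epiblast rose as a group (median 0.47, camera adjusted p = 7.03e-04, and adjusted p = 0.411 with an estimated correlation), as 11 of 16 rose, 3 fell and 2 did not pass, also when adjusted over the list alone. With siRNA #2 alone the list did not pass (camera adjusted p = 0.0647). Fgf5, a growth factor of the primed epiblast, rose by 2.60 (SE 0.15), Cdh2, N-cadherin, by 1.79 (SE 0.08), Wnt8a by 1.52 (SE 0.14) and Pou3f1 by 1.39 (SE 0.06). Otx2 rose by 0.48 (SE 0.06) in the mean of both, but was higher with siRNA #1 and lower with siRNA #2. Targets of Nodal, BMP and LIF signalling had 11 of 18 that rose, 4 that fell and 3 that did not pass, also when adjusted over the list alone (median 0.29, camera adjusted p = 0.0284, and adjusted p = 0.369 with an estimated correlation). That call was also lost when genes below the median signal were left out. The list as written also holds Spry2, Spry4, Dusp6, Etv4, Etv5 and Egr1, known as targets of FGF and ERK signalling. Its group call is therefore not one of Nodal, BMP and LIF targets alone. Within the list, Lefty2, a Nodal target and inhibitor, fell by 2.13 (SE 0.11), while Junb rose by 1.54 (SE 0.09) and Id2 and Id3, BMP targets, rose by 1.21 (SE 0.06) and 1.16 (SE 0.06). Sftpc, at -5.76, and the poly-A controls, at 0.90, moved in this contrast too.

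Other lineage lists did not pass as groups. For extraembryonic endoderm, 8 of 23 rose, 7 fell and 8 did not pass, with 8 fallen when adjusted over the list alone, and the median of -0.03, the mean of 0.01 and the upward direction of the test differed in sign (camera adjusted p = 0.727, and adjusted p = 0.882 with an estimated correlation). Sparc, a matrix protein, rose by 1.90 (SE 0.05) with 2 of 3 probe sets moving upwards, Col4a2, a basement membrane collagen, by 1.34 (SE 0.11) and Plat, tissue plasminogen activator, by 1.31 (SE 0.14), whereas Srgn, serglycin, fell by 1.55 (SE 0.15). Gata6 (-0.17, SE 0.15, adjusted p = 0.400) and Gata4 (-0.32, SE 0.15, adjusted p = 0.102) did not pass, and Gata4 passed with a variance fit without a trend. For primitive streak and mesoderm, 5 of 22 rose, 1 fell and 16 did not pass, also when adjusted over the list alone, and the median of -0.03 and the mean of 0.10 differed in sign (camera adjusted p = 0.716, and adjusted p = 0.842 with an estimated correlation). Tbx20, also read below the lower quartile of the control arrays, Wnt3 and Mesp2 rose by 1.38 (SE 0.15), 1.36 (SE 0.20) and 0.62 (SE 0.13), and Bmp4 fell by 0.76 (SE 0.07). For neural ectoderm, 7 of 22 rose, 5 fell and 10 did not pass, also when adjusted over the list alone (median 0.14, camera adjusted p = 0.0831, and adjusted p = 0.411 with an estimated correlation). Nefm, a neurofilament, Neurod1, Zic1 and Gap43 rose by 2.47 (SE 0.15), 1.71 (SE 0.05), 1.46 (SE 0.16) and 0.98 (SE 0.08).

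Markers of fibroblasts and feeder cells went both ways, with 7 of 23 that rose, 6 that fell and 10 that did not pass, also when adjusted over the list alone (median 0.16, camera adjusted p = 0.456, and adjusted p = 0.594 with an estimated correlation). Tagln and Vim, proteins of the actin and intermediate filament cytoskeleton, rose by 3.44 (SE 0.07) and 1.22 (SE 0.06). Col3a1 and Dcn, matrix genes that also stand in the lung mesenchyme list, fell by 2.54 (SE 0.18) and fell by 1.35 (SE 0.16), Col3a1 to readings below the lower quartile of the Ncl siRNA arrays.

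Genes of ribosome production moved by small amounts. Of 56 genes of ribosome biogenesis and the nucleolus, 27 fell, 9 rose and 20 did not pass, with 29 fallen when adjusted over the list alone, and the list fell as a group (median -0.10, camera adjusted p = 0.00861, and adjusted p = 0.594 with an estimated correlation). Ftsj3, Nop10, Noc4l and Polr1c, which act in ribosomal RNA processing or synthesis, fell by 0.84 (SE 0.06), fell by 0.73 (SE 0.04), fell by 0.71 (SE 0.06) and fell by 0.55 (SE 0.05), and the Noc4l call was lost when probe sets ending in _x_at or _s_at were left out. Npm1, another abundant nucleolar protein, did not pass (0.03, SE 0.03, adjusted p = 0.605). Among 43 measured cytosolic ribosomal protein genes, of 78 in the list, 19 fell, 3 rose and 21 did not pass, with 20 fallen when adjusted over the list alone. They fell as a group (median -0.08, camera adjusted p = 0.0251, and adjusted p = 0.423 with an estimated correlation). Rpl37, Rpl27a, Rpl14 and Rps6 fell by 0.79 (SE 0.08), fell by 0.67 (SE 0.08), fell by 0.58 (SE 0.06) and fell by 0.40 (SE 0.07). After quantile normalization of the deposited values neither list passed, and the ribosomal protein list did not pass without replicate 1 of the control siRNA, with adjusted p-values over the alternatives from 0.00317 to 0.304. These small shifts stood beside differences of 0.90 in the poly-A controls and 0.99 in 18S ribosomal RNA.

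In the DNA replication and S phase list 16 of 27 fell, 1 rose and 10 did not pass, also when adjusted over the list alone, and the list fell as a group (median -0.22, camera adjusted p = 3.68e-04, and adjusted p = 0.430 with an estimated correlation). Pola1, the catalytic subunit of DNA polymerase alpha, fell by 0.81 (SE 0.06) with 1 of its 2 probe sets moving downwards, Gins2 fell by 0.69 (SE 0.06), and Cdc6 fell by 0.63 (SE 0.06). Tyms, thymidylate synthase, fell by 0.63 (SE 0.15), a call lost with the mean of its 4 probe sets and without replicate 1 of the control siRNA. Genes of G2 and mitosis did not pass as a group (median -0.03, camera adjusted p = 0.727, and adjusted p = 0.882 with an estimated correlation), with 7 of 27 that rose, 9 that fell and 11 that did not pass, and 8 that rose when adjusted over the list alone. Anln, which acts in cytokinesis, rose by 0.83 (SE 0.04), and Birc5, Cdk1 and Aurkb fell by 0.67 (SE 0.05), fell by 0.61 (SE 0.05) and fell by 0.54 (SE 0.08). Cyclins and CDK inhibitors of G1 had 6 of 17 that rose, 6 that fell and 5 that did not pass, with 7 that rose when adjusted over the list alone (median 0.06, camera adjusted p = 0.0831, and adjusted p = 0.594 with an estimated correlation). This G1 list did pass under 3 of 10 alternatives of scaling, probe sets, signal filter, block or arrays left out. Ccnd2, Rb1 and Cdkn2b rose by 2.13 (SE 0.07), 1.80 (SE 0.06) and 1.53 (SE 0.10). Lung markers and poly-A controls separated the same arrays, with Scgb1a1 at -9.27 and the poly-A controls at 0.90.

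Of 25 Myc target genes outside the nucleolus, 15 fell, 6 rose and 4 did not pass, with 17 fallen and 7 risen when adjusted over the list alone. The list fell as a group (median -0.16, camera adjusted p = 0.0251, and adjusted p = 0.588 with an estimated correlation), a call also lost after quantile normalization of the deposited values. Shmt2, Shmt1 and Apex1 fell by 0.92 (SE 0.07), fell by 0.66 (SE 0.06) and fell by 0.43 (SE 0.04), and the Shmt2 call was lost when probe sets ending in _x_at or _s_at were left out. Cad, an enzyme of pyrimidine synthesis, rose by 0.57 (SE 0.06). Mycn rose by 0.28 (SE 0.04) with 2 of its 3 probe sets moving upwards, and Myc itself did not pass (0.04, SE 0.07, adjusted p = 0.667). The poly-A controls differed by 0.90 between these arrays, and the airway secretory median was -3.08.

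Cholesterol synthesis genes fell together, as 13 of 15 fell, none rose and 2 did not pass, also when adjusted over the list alone. The median was -0.66 (camera adjusted p = 1.16e-07, and adjusted p = 0.411 with an estimated correlation). Dhcr7, the last enzyme of the pathway, fell by 1.35 (SE 0.08), Insig1, a sterol sensor, fell by 1.11 (SE 0.08), and Nsdhl fell by 0.91 (SE 0.07). Lss, lanosterol synthase, fell by 1.13 (SE 0.08), a call lost when probe sets ending in _x_at or _s_at were left out. In the same contrast the airway secretory markers had a median of -3.08 and the alveolar type 2 markers -0.95, and the poly-A controls differed by 0.90. Glycolysis genes fell as a group (median -0.33, camera adjusted p = 0.0468, and adjusted p = 0.430 with an estimated correlation), with 8 of 14 that fell, 3 that rose and 3 that did not pass, also when adjusted over the list alone. Within the list the enzymes Pfkp and Tpi1 fell by 1.10 (SE 0.06) and fell by 0.78 (SE 0.05), and the glucose transporters Slc2a3 and Slc2a1 rose by 0.73 (SE 0.03) and 0.71 (SE 0.05). Genes of oxidative phosphorylation did not pass as a group (median -0.13, camera adjusted p = 0.0737, and adjusted p = 0.682 with an estimated correlation), although 13 of 25 fell, 7 rose and 5 did not pass, also when adjusted over the list alone. The list did pass under 2 of 10 alternatives of scaling, probe sets, signal filter, block or arrays left out. Uqcrc1, a subunit of complex III, rose by 0.62 (SE 0.04), and Cyc1, Cox6c and Atp5o fell by 0.39 (SE 0.05), fell by 0.38 (SE 0.04) and fell by 0.37 (SE 0.04).

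Oxidative stress response genes fell as a group (median -0.20, camera adjusted p = 0.0457, and adjusted p = 0.594 with an estimated correlation), with 11 of 19 that fell, 4 that rose and 4 that did not pass, also when adjusted over the list alone. Mgst1 and Sod2, antioxidant enzymes, fell by 1.39 (SE 0.13) and fell by 1.07 (SE 0.05), while Gpx3 and Hmox1, which also act against oxidants, rose by 2.44 (SE 0.07) and 0.98 (SE 0.08). The calls for glycolysis and for oxidative stress each ended under 5 of 10 alternatives of scaling, probe sets, signal filter, block or arrays left out, among them quantile normalization and the leaving out of replicate 1 of the control siRNA, with adjusted p-values up to 0.126. In the list of the integrated stress and unfolded protein response 6 of 24 rose, 8 fell and 10 did not pass, with 9 fallen when adjusted over the list alone (median -0.01, camera adjusted p = 0.716, and adjusted p = 0.882 with an estimated correlation). Atf3, a stress-induced transcription factor, rose by 3.21 (SE 0.09), and Nupr1, Phgdh and Chac1 fell by 1.77 (SE 0.15), fell by 1.08 (SE 0.06) and fell by 1.08 (SE 0.13). Of 21 interferon response genes 1 rose, 7 fell and 13 did not pass, also when adjusted over the list alone (median -0.19, camera adjusted p = 0.106, and adjusted p = 0.411 with an estimated correlation). Cxcl10, a chemokine, rose by 1.83 (SE 0.14), and Irf9 and Ifit2 fell by 1.07 (SE 0.12) and fell by 0.98 (SE 0.16). Eif2ak2, the kinase PKR, fell by 0.91 (SE 0.13) with 1 of its 3 probe sets moving downwards, a call lost with the mean of its probe sets. Macrophage and leukocyte markers, which lung tissue also holds, had a median of -0.36 in this contrast, and the poly-A controls differed by 0.90.

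In this comparison 14 of the 24 lists passed, 6 upwards and 8 downwards, and 0 passed with an estimated correlation. A directional fry test passed 19 lists. It asks whether the genes of a list move, on balance, in 1 direction, and does not set them against other genes.

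**Figure D3:**
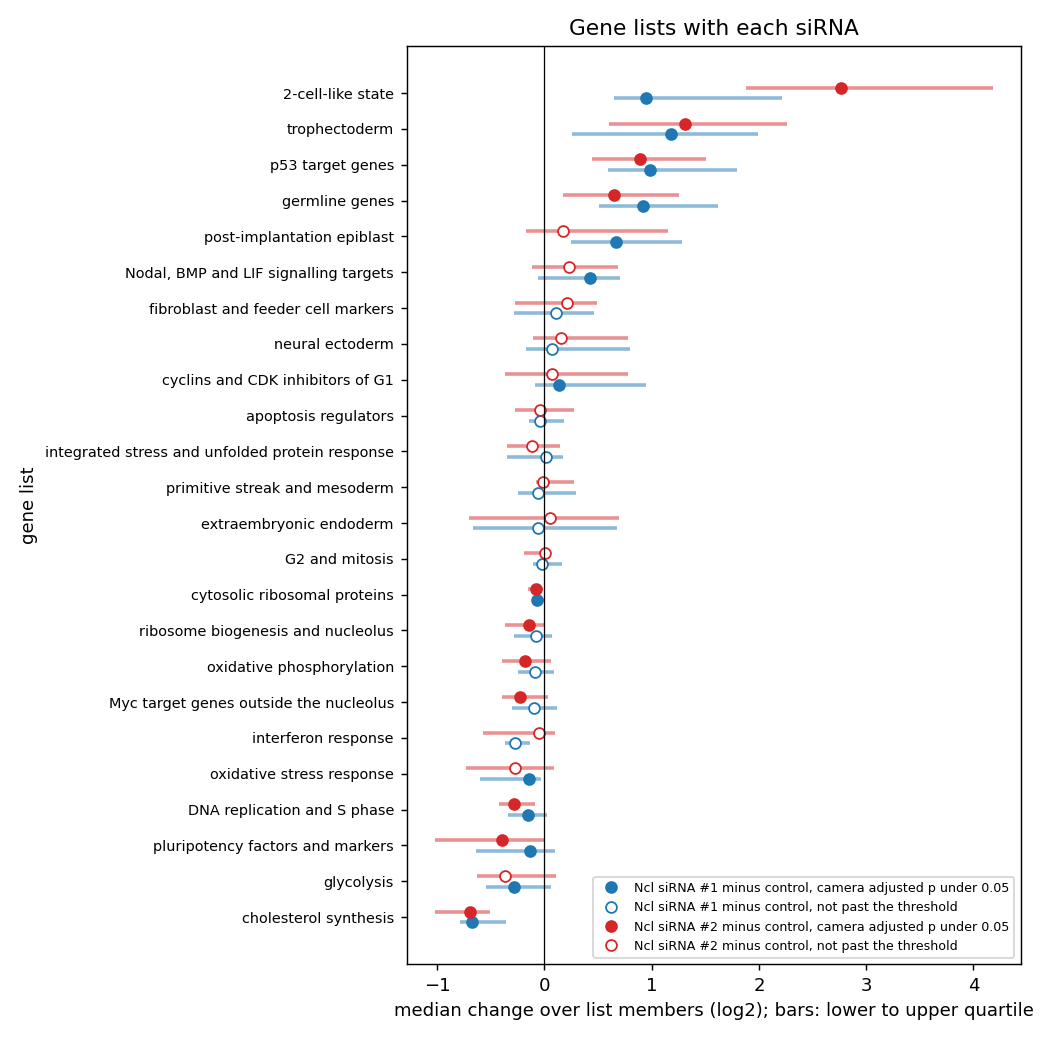
Median log2 change of the measured members of each of the 24 lists (horizontal axis, with bars from the lower to the upper quartile of the members) for Ncl siRNA #1 (blue) and Ncl siRNA #2 (red) against the control siRNA, with filled points for a camera adjusted p under 0.05 at the preset correlation. The 2-cell-like list had the highest median with siRNA #2, at 2.77 against 0.95 with siRNA #1, and 0 lists passed with an estimated correlation.

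With siRNA #1 alone, Thbs1 rose 18.1-fold over the control siRNA (log2 4.18, SE 0.11, n = 2 per group) and Plin2 15.1-fold (log2 3.92, SE 0.06). Fgf5 rose by 3.10 (SE 0.17) and Otx2, a transcription factor of the epiblast and of neural tissue, by 1.17 (SE 0.07). Among pluripotency genes Tcl1 fell by 1.83 (SE 0.10), Nanog fell by 0.45 (SE 0.05) and Pou5f1 fell by 0.35 (SE 0.05). In the same arrays Scgb1a1 fell by 9.47 (SE 0.16), and the lung airway secretory list had a median of -3.14. Limma called 6811 genes, 3668 of which rose and 3143 fell, and 856 and 232 of these met 2-fold. The balance turned after quantile normalization, where 3453 rose and 3701 fell. With each array centred on its median 3456 rose and 3323 fell.

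The p53 target list rose with siRNA #1 (27 of 31 rose, 2 fell and 2 did not pass, also when adjusted over the list alone, median 0.99, camera adjusted p = 2.39e-19). Its adjusted p was 0.0896 with an estimated correlation, as it was for trophectoderm and germline genes. Of 20 trophectoderm genes 13 rose, none fell and 7 did not pass, with 14 risen when adjusted over the list alone (median 1.18, camera adjusted p = 3.44e-09). Of 19 germline genes 14 rose, 1 fell and 4 did not pass, with 15 risen when adjusted over the list alone (median 0.92, camera adjusted p = 7.42e-07). Of 12 genes of the 2-cell-like state 10 rose and 2 did not pass, also when adjusted over the list alone (median 0.95, camera adjusted p = 3.27e-07, and adjusted p = 0.104 with an estimated correlation). Epiblast genes rose, with 12 of 16 up and 2 down, also when adjusted over the list alone (median 0.66, camera adjusted p = 3.50e-06, and adjusted p = 0.323 with an estimated correlation). Cholesterol synthesis genes fell, with 11 of 15 down and 4 not past the test, and 12 down and 1 up when adjusted over the list alone (median -0.67, camera adjusted p = 3.27e-07, and adjusted p = 0.349 with an estimated correlation).

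Pluripotency genes fell as a group with siRNA #1, with 14 of 28 down and 7 up, also when adjusted over the list alone (median -0.13, camera adjusted p = 0.0118, and adjusted p = 0.524 with an estimated correlation). DNA replication genes fell, with 13 of 27 down and none up, and 14 down and 1 up when adjusted over the list alone (median -0.15, camera adjusted p = 0.00440, and adjusted p = 0.526 with an estimated correlation). Nodal, BMP and LIF targets rose (12 of 18 up, 4 down, also when adjusted over the list alone, camera adjusted p = 0.0133), and so did G1 cyclins and CDK inhibitors (8 of 17 up, 4 down, also when adjusted over the list alone, camera adjusted p = 0.0223). These were at adjusted p = 0.269 and adjusted p = 0.526 with an estimated correlation. Glycolysis genes fell (8 of 14 down, 2 up, with 3 up when adjusted over the list alone, camera adjusted p = 0.0298), as did oxidative stress genes (12 of 19 down, 4 up, also when adjusted over the list alone, camera adjusted p = 0.0315) and ribosomal proteins (12 of 43 down, 3 up, also when adjusted over the list alone, camera adjusted p = 0.0315). With an estimated correlation these were at adjusted p = 0.432, adjusted p = 0.593 and adjusted p = 0.465. Each of these last 5 calls ended under at least 1 alternative. Median, mean and test differed in sign for the primitive streak, apoptosis and integrated stress lists, none of which passed. In all 13 lists passed, 7 upwards and 6 downwards, and 16 passed with fry.

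With siRNA #2 alone, genes of the 2-cell-like state had the highest list median. Usp17la rose 51.4-fold over the control siRNA (log2 5.68, SE 0.11, n = 2 per group) and Zfp352 17.7-fold (log2 4.14, SE 0.13). Cdx2, the trophectoderm factor, rose by 2.22 (SE 0.16), and Krt18 by 4.25 (SE 0.07). Tcl1 fell by 2.28 (SE 0.10), Nanog fell by 0.72 (SE 0.05), Pou5f1 fell by 0.57 (SE 0.05) and Lefty2 fell by 2.66 (SE 0.13). Lung genes were low again, with Scgb1a1 at -9.06 (SE 0.16) and an airway secretory list median of -3.02. Limma called 7180 genes, of which 3228 rose and 3952 fell, and 882 and 403 of these met 2-fold.

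Of 12 genes of the 2-cell-like state 10 rose with siRNA #2 and 2 did not pass, also when adjusted over the list alone (median 2.77, camera adjusted p = 1.08e-11). Trophectoderm genes rose, with 17 of 20 up and none down, also when adjusted over the list alone (median 1.31, camera adjusted p = 1.11e-12), and both lists were at adjusted p = 0.0990 with an estimated correlation. The p53 targets rose with 25 of 31 up and 3 down, also when adjusted over the list alone (median 0.89, camera adjusted p = 3.55e-15), and germline genes with 11 of 19 up and 1 down, and 12 up when adjusted over the list alone (median 0.65, camera adjusted p = 5.17e-05). Both were at adjusted p = 0.109 with an estimated correlation. Cholesterol synthesis genes fell (13 of 15 down, none up, also when adjusted over the list alone, median -0.70, camera adjusted p = 5.08e-08), as did pluripotency genes (18 of 28 down, 5 up, also when adjusted over the list alone, median -0.40, camera adjusted p = 3.38e-05). Both were at adjusted p = 0.455 with an estimated correlation. Epiblast genes did not pass with this siRNA (8 of 16 up, 5 down, also when adjusted over the list alone, median 0.17, camera adjusted p = 0.0647, and adjusted p = 0.532 with an estimated correlation). They did pass under 4 of 10 alternatives of scaling, probe sets, signal filter, block or arrays left out.

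DNA replication genes fell with siRNA #2 (17 of 27 down, 1 up, also when adjusted over the list alone, median -0.28, camera adjusted p = 5.17e-05, and adjusted p = 0.471 with an estimated correlation). Ribosome biogenesis genes fell, with 29 of 56 down and 5 up, and 31 down and 6 up when adjusted over the list alone (median -0.14, camera adjusted p = 7.37e-04, and adjusted p = 0.532 with an estimated correlation). Myc targets fell, with 17 of 25 down and 6 up, and 18 down when adjusted over the list alone (median -0.22, camera adjusted p = 0.00689, and adjusted p = 0.485 with an estimated correlation). Ribosomal proteins fell with 17 of 43 down and 1 up, also when adjusted over the list alone (median -0.08, camera adjusted p = 0.0281, and adjusted p = 0.471 with an estimated correlation). Oxidative phosphorylation genes fell with 16 of 25 down and 5 up, and 17 down and 6 up when adjusted over the list alone (median -0.18, camera adjusted p = 0.0281, and adjusted p = 0.629 with an estimated correlation). The calls for ribosomal proteins and oxidative phosphorylation ended after quantile normalization and when genes below the median signal were left out, and that for ribosomal proteins also without replicate 1 of the control siRNA or replicate 1 of siRNA #2. Median, mean and test differed in sign for the primitive streak, G2 and mitosis and apoptosis lists, none of which passed. In all 11 lists passed, 4 upwards and 7 downwards, and 22 passed with fry.

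Across genes the changes with the 2 siRNAs went together, as 5423 genes changed in the same direction with each, 2827 upwards and 2596 downwards, against 11 in opposite directions. The balance turned with scaling, to 2876 upwards and 3065 downwards after quantile normalization, and 2524 and 2773 after median centring. Ccn1 rose 16.9-fold with siRNA #1 and 19.9-fold with siRNA #2, and Cdkn1a 5.10-fold and 5.26-fold. If the calls had been independent, 651 genes upwards and 683 downwards would be shared. A change of at least 2-fold with each siRNA was met by 710 genes that rose and 209 that fell. The log2 changes had a Pearson r of 0.92 across genes, which are not independent replicates, with a covariance of 0.29. Both comparisons used the same control arrays. In 50 simulations without any siRNA effect, independent noise was drawn for each gene and array. Noise in the shared arrays gave a mean r of 0.50, a mean covariance of 0.00949 and 0 genes called with both. An offset common to both control arrays was not simulated, so the 0 cannot bear on it. Part of the excess may come from the shared controls. With 1 control array for each siRNA, a split chosen after the results were seen, r was 0.85 and the covariance 0.28 in both assignments, and 4227 or 4327 genes changed in the same direction. A lone control array is there assumed to vary like the siRNA arrays, and what both control arrays hold in common stays shared. In those arrays Scgb1a1 and other lung genes were higher than in all Ncl siRNA arrays.

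**Figure D4:**
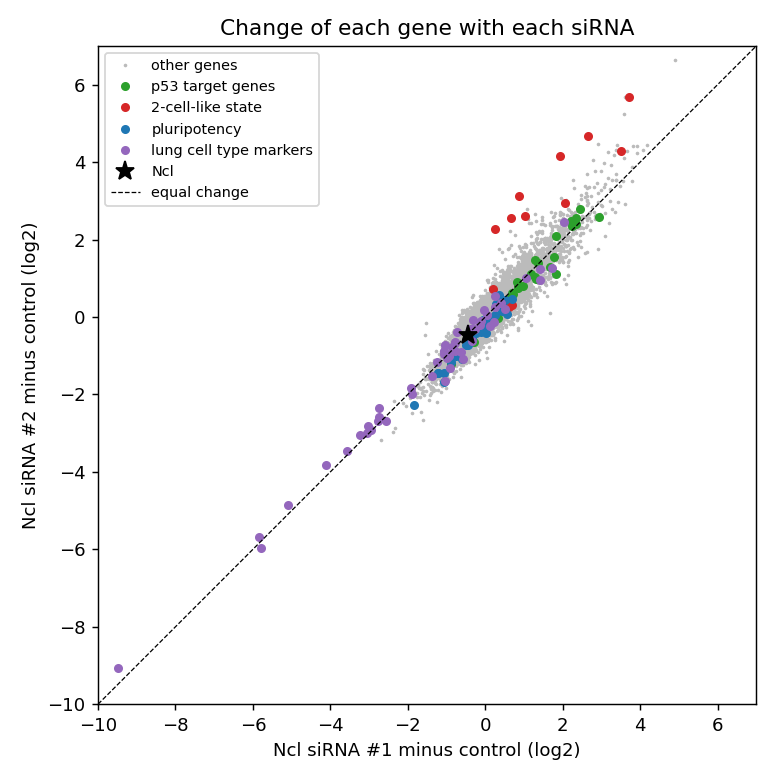
Log2 change of each of 18194 genes with Ncl siRNA #1 (horizontal axis) and Ncl siRNA #2 (vertical axis) against the same control arrays, with 1 point per gene, colours for 4 gene groups and a dashed line of equal change. Most points lay near the line (r 0.92 across genes), lung cell markers reached -9.47 with siRNA #1, and several genes of the 2-cell-like state lay above the line.

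The 2 Ncl siRNAs were compared directly to ask where their effects differed. The control arrays were no part of the difference but entered its pooled spread. A fit to the siRNA arrays alone gave 1525 differing genes, against 1543 in the main fit. Genes of the 2-cell-like state and of the trophectoderm were higher with siRNA #2, and genes of pluripotency and of the post-implantation epiblast were lower. All 4 group calls were lost with an estimated correlation. Tcstv1 was higher by 2.26 (SE 0.16, n = 2 per group, limma adjusted p = 1.06e-08), Zfp352 by 2.22 (SE 0.13, limma adjusted p = 2.42e-10), and Tcstv3 and Tdpoz1 by 2.02 (SE 0.17) and 2.01 (SE 0.19). BC080696 was higher by 2.08 (SE 0.14) and Usp17la by 1.96 (SE 0.11). Otx2, which rose by 1.17 over control with siRNA #1 and fell by 0.20 with siRNA #2, was lower with siRNA #2 by a log2 difference of -1.37 (SE 0.07, limma adjusted p = 6.39e-11). The difference was -1.56 (SE 0.17) for Aspa, aspartoacylase, -1.24 (SE 0.11) for Cd59a, a complement inhibitor, -1.16 (SE 0.16) for Syce3, a synaptonemal complex protein, and -1.15 (SE 0.16) for Pla2g4a, a phospholipase. Siglecf, a sialic acid receptor read near the lower end of the range, differed by -1.20 (SE 0.21), a call lost with a variance fit without a trend.

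Of 12 genes of the 2-cell-like state 9 were higher with siRNA #2 and 3 did not pass, and 10 were higher and 1 lower when adjusted over the list alone (median 1.73, camera adjusted p = 5.55e-19, and adjusted p = 0.0924 with an estimated correlation). The probe set annotated to 6 symbols was higher by 1.21 (SE 0.07). In the trophectoderm list 8 of 20 were higher and 12 did not pass, with 9 higher and 1 lower when adjusted over the list alone (median 0.30, camera adjusted p = 2.35e-08, and adjusted p = 0.145 with an estimated correlation). Cdx2 was higher by 0.84 (SE 0.16) and Krt18 by 1.08 (SE 0.07). Pluripotency genes were lower, with 19 of 28 lower and 1 higher, and 22 lower when adjusted over the list alone (median -0.22, camera adjusted p = 4.27e-11, and adjusted p = 0.359 with an estimated correlation). Prdm14 differed by -0.63 (SE 0.12), Nanog by -0.27 (SE 0.05) and Pou5f1 by -0.23 (SE 0.05). Epiblast genes were lower, with 8 of 16 lower and 1 higher, also when adjusted over the list alone (median -0.32, camera adjusted p = 3.73e-05, and adjusted p = 0.467 with an estimated correlation). Fgf5 differed by -1.01 (SE 0.17).

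Another 8 lists passed with smaller differences, and none of them passed with an estimated correlation. Ribosome biogenesis genes were lower with siRNA #2, with 7 of 56 lower and none higher, and 13 lower when adjusted over the list alone (median -0.11, camera adjusted p = 1.19e-04). DNA replication genes were lower with 4 of 27 lower, and 5 when adjusted over the list alone (median -0.13, camera adjusted p = 0.00114), oxidative phosphorylation genes with 4 of 25, and 8 when adjusted over the list alone (median -0.11, camera adjusted p = 0.00219), and Myc targets with 4 of 25, and 10 lower and 1 higher when adjusted over the list alone (median -0.08, camera adjusted p = 0.00350). G1 cyclins and CDK inhibitors were lower with 5 of 17 lower and 1 higher, also when adjusted over the list alone (camera adjusted p = 0.0464), and extraembryonic endoderm genes were higher with 3 of 23 higher and 2 lower, and 6 and 3 when adjusted over the list alone (camera adjusted p = 0.0464). All 6 of these lists were at adjusted p = 0.531 with an estimated correlation. Germline genes were lower with 3 of 19 lower, and 4 when adjusted over the list alone (camera adjusted p = 0.0226, and adjusted p = 0.388 with an estimated correlation), and cholesterol synthesis genes with 1 of 15, and 2 when adjusted over the list alone (camera adjusted p = 0.0289, and adjusted p = 0.547 with an estimated correlation). Of these 8 lists, 7 also lost their call under at least 1 alternative of scaling, probe sets, signal filter or arrays left out, and that of ribosome biogenesis was lost with fry (adjusted p = 0.107). The p53 targets did not pass (3 of 31 higher, 7 lower, with 11 lower when adjusted over the list alone, median -0.12, camera adjusted p = 0.0945, and adjusted p = 0.531 with an estimated correlation).

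In all 1543 genes differed between the siRNAs, 418 higher and 1125 lower with siRNA #2, and 56 of them by at least 2-fold, 40 higher and 16 lower. The balance of directions depended on the processing, with 567 higher and 596 lower after quantile normalization and 82 and 60 with a variance fit without a trend. The count depended on single arrays, since it was 732 without replicate 1 of siRNA #1, 4301 without replicate 2 of siRNA #1, 451 without replicate 1 of siRNA #2 and 483 without replicate 2 of siRNA #2, and the fit without a trend gave 142. Of the 5423 genes changed in the same direction with each siRNA, 891 differed between them, and 64.4% of the 5423 had the larger change with siRNA #2, while the slope of siRNA #2 on siRNA #1 changes over all genes was 0.995. In all 12 lists passed, 3 upwards and 9 downwards, and 5 passed with fry. Scgb1a1 did not pass between the siRNA groups (0.41, SE 0.16, limma adjusted p = 0.114), and the poly-A controls differed by -0.29. Median, mean and test differed in sign for the neural ectoderm, oxidative stress and interferon lists, none of which passed.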

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

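The tests of explanations in this part were chosen after the results were seen, while the comparison of the siRNAs and the p53 and 2-cell-like lists were fixed before the data were examined.

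The siRNAs differed in several genes by a direct test of siRNA #2 minus siRNA #1. The log2 difference was 2.26 for Tcstv1, 2.22 for Zfp352, 2.08 for BC080696, 2.02 for Tcstv3, 2.01 for Tdpoz1 and 1.96 for Usp17la, and -1.56 for Aspa, -1.37 for Otx2, -1.24 for Cd59a, -1.20 for Siglecf, -1.16 for Syce3 and -1.15 for Pla2g4a. Outside the gene tests, the poly-A controls read 0.90 higher and 18S ribosomal RNA 0.99 higher in the Ncl siRNA arrays than in the control arrays. A probe set annotated to several genes, some of them in the 2-cell-like list, read 5.89 higher.

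The control arrays stood apart in lung genes and in added control RNAs. Broad differentiation of the control cells into most of the other organs listed is argued against, since only heart muscle, 1 of 9 such lists, had a median below -0.5. Of 7 lists of lung cell types 5 did. The lung lists were written after the lowest genes were seen and hold most of them, so that count is no independent support. Differentiation into a few cell types, such as heart muscle, endothelium and mesenchyme, stays open. In the alveolar type 2 list 6 of 9 measured genes were lower and 1 was higher, although Sftpb stayed near 6.92 in the control arrays. Lung tissue RNA, or its labelled copy, in the control arrays would give the 5 low lung lists. Separate processing of the control arrays would give the poly-A difference of 0.90. Loss of lung gene expression in stem cells through the Ncl siRNAs cannot be told apart from these, as the median over the genes of a lung list of siRNA #2 minus siRNA #1 was at most 0.12, even for lung mesenchyme with list medians of -1.04 and -1.66 against control, and no other sample without an Ncl siRNA was measured. Any gene that lung tissue also expresses could therefore owe part of its fall to the control arrays.

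Target genes of p53 rose as a group with both siRNAs at the preset correlation of camera, a call lost with an estimated correlation (adjusted p = 0.0896 with siRNA #1 and adjusted p = 0.109 with siRNA #2). Dilution of stem cell RNA by foreign RNA in the control arrays is argued against as the only cause. The p53 list median lay 1.14 above that of the pluripotency list. The lower quartile of the p53 list (0.52) also lay above the upper quartile of the pluripotency list (0.05). A fall of pluripotency genes with the siRNAs could hide a rise through dilution, so dilution as a part of the p53 rise stays open. Random lists of the same size and similar expression had a 99th percentile of 0.18, and 0 of 10000 reached the p53 median of 0.89. Separate processing of the control arrays still cannot be told apart from an effect of the siRNAs, since all control arrays share it. Activation of p53 through loss of nucleolin, and a response to the Ncl duplexes themselves, both stay open.

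Genes of the 2-cell-like state were higher as a group with siRNA #2 than with siRNA #1 at the preset correlation of camera, a call lost with an estimated correlation (adjusted p = 0.0924). Deeper loss of the Ncl transcript with siRNA #2 was not seen in the mean difference over the Ncl probe sets, 0.0442 (95% confidence interval -0.11 to 0.20). That interval runs across probe sets of the same arrays, which are not replicates. Single probe sets differed by -0.15 (SE 0.08) to 0.15 (SE 0.18), and none passed, so a small difference in loss stays open. Cross-hybridisation within 1 repeated gene family is argued against as the source of the whole difference. On probe sets not ending in _x_at or _s_at, 9 members with 8 different name stems passed. These stems are not all repeated families, and cross-hybridisation within each repeated family stays open. A sequence-specific effect of either duplex, or a different loss of nucleolin protein, could still produce the difference, and neither was measured here.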

How the results depend on the processing

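Apart from the lung and heart muscle alternative and the split of the control arrays, which were chosen after the results were seen, these alternatives were fixed before the data were examined. The Ncl change kept its direction and its call under the alternatives set for it, which held no fold threshold. On its brightest probe set, at -0.46 with each siRNA, it does not reach 2-fold. Of 2475 recomputed values of named genes 2417 kept their call, 53 no longer passed, 4 newly passed, and 1 changed sign, Bmf, at 0.00943 without probe sets ending in _x_at or _s_at. As most named genes were chosen for large changes in these arrays, their kept calls do not describe other called genes. By construction, at least 2-fold gave 1088 genes with siRNA #1, 1285 with siRNA #2, 1136 with the mean of both, 919 in the same direction with each and 56 between the siRNAs, and an adjusted p under 0.01 gave 633 between the siRNAs. All probe sets, which are more features, gave 12271 calls with siRNA #1, 12882 with siRNA #2, 14236 with the mean of both and 9543 in the same direction with each. Between the siRNAs the same fit gave 1306, fewer than the 1543 of the main fit. The 1543 genes between the siRNAs became 790 with the mean of all probe sets and 142 without a variance trend, where the cause was not tested. Their share higher with siRNA #2 was 27.1%, 48.8% after quantile normalization and 17.9% after median centring, so that the balance of directions depends on scaling. Without single arrays this count ranged from 451 (without replicate 1 of siRNA #2) to 4301 (without replicate 2 of siRNA #1), with 732 without replicate 1 of siRNA #1 and 483 without replicate 2 of siRNA #2. There a lone array is assumed to vary like the other groups. Other counts ranged without single arrays from 5565 to 7599 (siRNA #1), 5553 to 8003 (siRNA #2), 6226 to 8419 (mean of both) and 4528 to 5666 (same direction). Lists with the mean of both fell from 14 to 9 after quantile normalization, and between the siRNAs from 12 to 7 without genes below the median signal; the cause was not tested. With an estimated correlation 0 lists passed with siRNA #1, 0 with siRNA #2, 0 with the mean of both and 0 between the siRNAs. Fry passed 22 lists with siRNA #2 and 5 between the siRNAs. The replicate block gave 6872, 7184, 7632 and 1611 genes. Correlations between arrays sharing a number, taken after each gene's group mean was removed, were -0.02, 0.00 and 0.01. Lung and heart muscle markers were dropped only after the fit. The counts were then 6759, 7128, 7593 and 5375, with every call shared with the main results. This cannot show whether the control arrays shifted the other genes. With 1 control array for each siRNA, the log2 changes of the 2 siRNAs had r of 0.85 in both assignments. A pseudocount was not run because the values are already log2, and a fit to only the groups compared is not possible for the mean of both. Without detection calls, signal over background could not be judged for dim genes.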

Other observations

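The lists in this part and their tests were chosen after the results were seen, and its genes were chosen after their values were seen.

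With the mean of both siRNAs against control, 13 of 18 target genes of YAP and TEAD rose and none fell (median 0.96, camera adjusted p = 1.48e-10, and adjusted p = 0.0289 with an estimated correlation). Axl, a receptor kinase, rose by 3.03 (SE 0.18), Amotl1 by 2.77 (SE 0.07) and Ccn2, a secreted matrix protein, by 2.48 (SE 0.04). Without the 1 member named before, the group test gave camera adjusted p = 4.55e-09, and adjusted p = 0.0373 with an estimated correlation. As the list was written after the values were seen, neither test is independent support for a rise of YAP and TEAD targets. Of 18 genes of SRF and the actin cytoskeleton 16 rose and 1 fell (median 0.99, camera adjusted p = 2.15e-13, and adjusted p = 0.0638 with an estimated correlation), among them Tpm1, tropomyosin, by 3.06 (SE 0.05) and Fhl2 by 2.19 (SE 0.10). All these changes were measured against the 2 control arrays that stood apart in lung genes (airway secretory median -3.08), in poly-A controls (0.90), in 18S ribosomal RNA (0.99) and in the 3′ minus 5′ difference of Actb, itself a cytoskeleton gene (0.48 against 0.25).

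Of 18 imprinted genes 12 rose and 1 fell (median 0.45), and they passed as a group at the preset correlation (camera adjusted p = 9.24e-06) but not with an estimated correlation (adjusted p = 0.0638), in a list also written after the values were seen. Igf2, a fetal growth factor, rose by 3.87 (SE 0.05) and Sgce by 2.69 (SE 0.09), while Phlda2, which restrains placental growth, fell by 1.36 (SE 0.06). Simple epithelial adhesion genes rose, with 11 of 16 up and 3 down (median 0.43, camera adjusted p = 1.21e-04, and adjusted p = 0.122 with an estimated correlation), such as Dsp, desmoplakin, by 3.29 (SE 0.07) and Cdh3, P-cadherin, by 2.00 (SE 0.09). Lysosome genes did not pass, with 8 of 16 up and 7 down (median 0.01, camera adjusted p = 0.767, and adjusted p = 0.913 with an estimated correlation). Ctsd rose by 1.71 (SE 0.05) and Glb1 fell by 1.18 (SE 0.09).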
